A study of Sarcophaga crassipalpis with 16 samples.

How the data were processed

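Whole pupae of Sarcophaga crassipalpis, 5 days old, were the samples. Per the labels' protocols, each pupa was broken up with beads, total RNA was extracted with a lipid tissue kit and treated with DNase, and 100 ng was mixed with 10 spike-in transcripts and labelled as Cy5 or Cy3 cRNA. The labels give 4 groups (control and parasitized, at 3 h and 25 h) of 4 pupae. The series text also speaks of 16 individuals per sample; since the protocol describes extraction from a single pupa, this was read as 16 individuals in all. Each array compared 2 pupae of a loop, and loops 1 and 3 ran in the opposite dye direction from loops 2 and 4. Slide 1 held loops 1 and 2 and slide 2 held loops 3 and 4.

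Per the file headers, each array was read with Agilent Feature Extraction 10.7.3.1, a version that the submitters' processing notes give too. The deposited intensity values used were the mean spot brightness and the median local background of each channel, neither yet subtracted. The processed intensity values, per the file headers background-subtracted and dye-normalized by the same program, served as an alternative. The deposited log10 ratio of Cy5 over Cy3 was used only to find the scale and direction of the authors' value table. The authors' value table holds log2 ratios: in every array its values were the log2 ratio of the processed Cy5 over Cy3 signal, averaged over the spots of a probe (r = 1, largest median absolute difference 2.2e-16), so scale and direction are known, and no further centring was applied. Its column medians were -0.14, -0.13, 0.01 and 0.05 for the arrays with the Cy5 pupae control_3h, parasitized_3h, parasitized_25h and control_25h of replicate 1. They were -0.11, 0.08, -0.20 and -0.15 for control_3h, control_25h, parasitized_25h and parasitized_3h of replicate 2. They were 0.00182, -0.08, 0.03 and -0.05 for control_3h, parasitized_3h, parasitized_25h and control_25h of replicate 3. They were 0.07, 0.03, -0.04 and -0.07 for control_3h, control_25h, parasitized_25h and parasitized_3h of replicate 4.

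Each array held 15744 spots, 15208 of them for 10123 probes that are not controls, and 5085 probes had 2 spots. Every one of the 10123 probes is described as unknown in the files. No annotation was used here, so no probe was named by gene. The 23 gene lists drawn up before the data were examined (immune, stress, hormone, cuticle, metabolic and other lists) were therefore not tested, and each probe was treated as its own feature. Named probes followed a rule set at the same time for files without gene names: at most 2 higher and 2 lower per comparison, with the same sign in all 4 loops. Of these, the largest changes past the threshold were taken, or the smallest p where none passed.

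From the deposited intensities, the background was corrected with normexp (offset 50) and each array was normalized with loess, control spots having weight 0, in limma 3.58.1 and R 4.3.3. Spots flagged as outliers were left out, and spots of a probe were averaged. In each loop, the 4 log2 ratios were solved for 3 differences between pupae and 1 dye term. The resulting pupa values were fitted in limma with group and loop as terms (9 residual degrees of freedom), followed by eBayes and Benjamini-Hochberg adjustment over the probes tested, with a threshold of 0.05. The loop is a block because a ratio exists only within a loop, and since each slide holds whole loops, this also removes slide. A probe was tested if at least 4 of the 8 readings of 1 group were well above background, which left 5815 probes (57.4%); 4291 were dim in all groups and 19 lacked a log ratio. Levels of single pupae are means of both dye readings after loess and Aquantile normalization, without the loop term, so differences between group means can deviate slightly from the fitted ones. A bound written as "at least" sets the mean of the brighter group against the higher of the dim probe's own level and the lowest level well above background. The 6 comparisons were parasitized against control at 3 h and at 25 h, the mean of both, their difference, and 25 h against 3 h in each condition.

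The readings were checked before use. In 16 of 16 pupae the Cy3 reading was most like the Cy5 reading of the same pupa, with a correlation across probes of at least 0.997; the highest correlation between readings of different pupae was 0.9968. The spike-in transcripts had slopes of 0.941 to 0.959 against their known ratios. The SD of the log2 ratio of an array, from the closure of the loops, was 0.0554, against a median residual SD between pupae of 0.0829.

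The procedure was tested on simulated data with 5815 probes, 50 of them changed at each of 4 sizes. Log2 changes of 0.5, 1, 2 and 4 were recovered in 78%, 84%, 100% and 98% of probes at 3 h, in 94%, 92%, 96% and 100% at 25 h, and in 84%, 90%, 96% and 98% for time in control pupae. Of all calls in the simulation, 3.74%, 4.02% and 4.66% were false. The simulated noise was drawn independently for each probe and pupa. These rates therefore do not carry over to probes that vary together between pupae, as many did here.

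The alternatives, all but those named as later additions fixed before the data were examined, changed the background correction, the normalization within and between arrays, the values used, the filter on dim probes and the design (no loop term, slide as a term, 16 ratios as independent, a separate-channel model with statmod 1.5.0 on 32 readings, each slide alone). They also left out each loop and each pupa.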

Results

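Gene expression was measured in whole pupae of the flesh fly Sarcophaga crassipalpis that had or had not been parasitized by Nasonia vitripennis, a wasp that stings the pupa and lays its eggs on it under the puparium. The pupae were 5 days old, and the labels give time points of 3 h and 25 h. Each of the 4 groups held 4 pupae, and the labels state that RNA came from single individuals, so that a replicate is a pupa. The 16 pupae were compared on 16 arrays of 60-base probes with 2 dyes, in 4 closed loops of 4 arrays. Each loop held 1 pupa of each group, and each pupa was read once in Cy5 and once in Cy3. Between 50% and 55.5% of the spots were well above background in Cy5 and between 45.2% and 55.4% in Cy3, and no spot was saturated. Of 10123 probes, 5815 were bright enough to be tested. The files name no genes, so probes are given by their identifier and sequence, and the identifiers are printed without their common ending PI426902900. The number of pupae, 4 per group, limits the precision.

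The comparison of parasitized with control pupae at 3 h addressed the earlier time point. The labels do not say from which event the times are counted. The 2 probes with the smallest p among those higher in parasitized pupae of all 4 loops were CUST_5106 (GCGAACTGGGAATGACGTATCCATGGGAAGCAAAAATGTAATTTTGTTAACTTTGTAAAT), with a log2 difference of 0.32 ± 0.06 (SE, n = 4 pupae per group; limma's adjusted p = 0.16), and CUST_2473, with 0.17 ± 0.03 (limma's adjusted p = 0.16). On the lower side, CUST_3382 (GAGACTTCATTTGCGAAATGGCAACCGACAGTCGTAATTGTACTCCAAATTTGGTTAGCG) had a log2 level of 12.91 ± 0.33 (SD, n = 4) in controls and 12.40 ± 0.09 (SD, n = 4) in parasitized pupae, a difference of -0.53 ± 0.10 (SE; limma's adjusted p = 0.16), and CUST_5355 had -0.24 ± 0.05 (SE; limma's adjusted p = 0.16). None of these passed the threshold of 0.05. By limma, 0 of the 5815 probes passed, while 1178 had an unadjusted p under 0.05, against 291 expected on average if no probe differed. Many probes varied together between pupae, so a count by chance can lie far from 291, and the excess is not a test. Of the 1178, 447 were higher and 731 lower in parasitized pupae. With a set of 155 probes left out, which stood at separate levels in different pupae, the unadjusted count was 1027, and with the level of the set also used as a covariate it was 471; 0 passed in both. No probe was above background in all 8 readings of one of these groups and in none of the other. With control_3h replicate 2 left out, 701 probes passed, 123 higher and 578 lower in parasitized pupae, and they included all 155 probes of that set. This pupa was the only 3 h control at the lower level of the set, where all 4 parasitized 3 h pupae stood. Without it, group and level coincide, so the 155 calls follow from the levels and the other calls cannot be told apart from them. With pupae weighted by their fit, an alternative chosen after seeing the data, 859 passed here, 213 higher and 646 lower. Neither slide alone gave a call at 3 h, while models that take arrays and not pupae as the replicates gave 614 (on ratios) and 1159 (on separate channels).

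At 25 h, the largest difference among the named probes was that of CUST_8208 (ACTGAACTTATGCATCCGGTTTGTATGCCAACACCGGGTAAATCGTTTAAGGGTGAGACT). Its log2 level was 6.77 ± 0.40 (SD, n = 4) in control pupae and 8.60 ± 0.51 (SD, n = 4) in parasitized pupae, a 3.36-fold difference (log2 1.75 ± 0.25, SE). It was higher in the parasitized pupa of all 4 loops, and limma's adjusted p was 0.059. CUST_3275 was above background in 4 of the 8 readings of the parasitized group and in 0 of the 8 of the controls, at least 1.15-fold higher (limma's adjusted p = 0.059). CUST_2110 (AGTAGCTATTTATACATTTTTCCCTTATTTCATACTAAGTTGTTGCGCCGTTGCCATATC) had a difference of -0.48 ± 0.09 (SE; limma's adjusted p = 0.088), from 9.76 ± 0.11 in controls to 9.31 ± 0.20 in parasitized pupae (SD, n = 4). CUST_6504 had -0.17 ± 0.03 (SE; limma's adjusted p = 0.088). By the background flags alone, 1 probe was above background in all 8 readings of the parasitized group and in none of the controls, and 0 the other way round. It was CUST_2588, chosen after its values were seen, at least 1.07-fold higher (limma's adjusted p = 0.32). By limma, 0 of 5815 probes passed. At an unadjusted p under 0.05 there were 937, of which 621 were higher and 316 lower in parasitized pupae. With the log ratios scaled between arrays and all pupae kept, 166 passed, 136 higher and 30 lower, among them CUST_8208, CUST_3275, CUST_2110 and CUST_6504. With all pupae kept and weighted by their fit, 1241 passed, 732 higher and 509 lower; the weights were chosen after seeing the data, and parasitized_25h replicate 1 had 0.45 and replicate 3 had 4.92.

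The count at 25 h also changed when 1 pupa was left out. Without parasitized_25h replicate 1, 525 probes passed limma's threshold, 389 of them higher and 136 lower in the other 3 parasitized pupae. The median log2 difference of the 389 was 0.33, and that of the 136 was -0.25. All 389 and all 136 had the same sign with all pupae in the fit. That fit holds the same pupae and 1 more, so this is no separate support. Of the 525, 8 were at least 4-fold higher, by log2 2.26 to 4.06, and 0 were at least 4-fold lower. Over these 8 probes the median level above the 25 h control mean was log2 2.97, 2.44 and 3.06 in parasitized replicates 2, 3 and 4, and 0.08 in replicate 1, while the 4 control pupae lay between -0.14 and -0.01. The 8 probes were picked by their difference in replicates 2 to 4. CUST_8208 had a log2 difference of 1.92 without replicate 1 (limma's adjusted p = 0.0017; 4.9e-06 to 1 over 39 alternatives), and with all pupae it was the only probe past the threshold in the scanner's processed signals and in the authors' values (log2 2.83; limma's adjusted p = 0.021 in both). Leaving out any 1 of the other 15 pupae gave 0 or 1 probes. Slide 1 alone gave 0 probes and slide 2 alone gave 4, and the models with arrays as replicates gave 370 and 914.

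**Figure D1:**
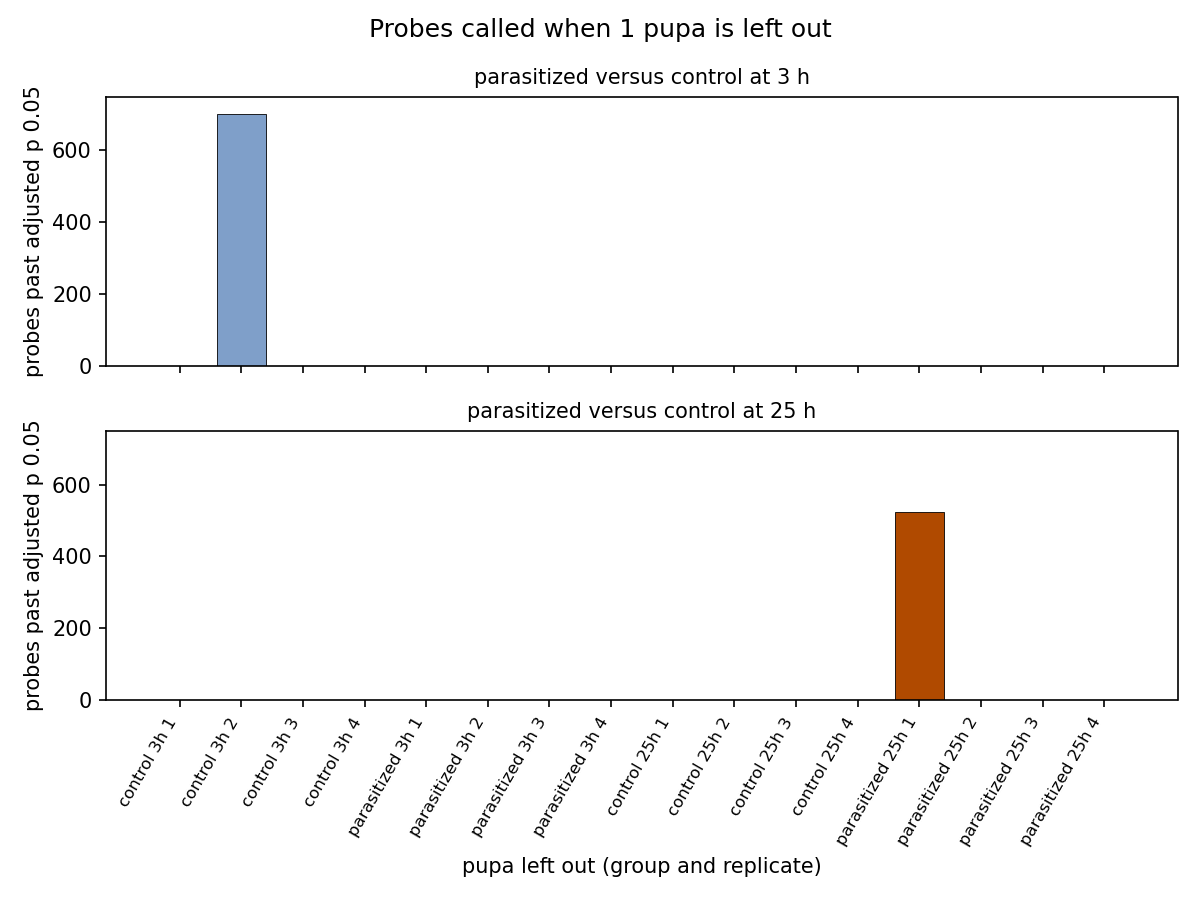
Number of probes past limma's adjusted p of 0.05 (vertical axis) in the comparison of parasitized with control pupae at 3 h (top) and 25 h (bottom), with the pupa named on the horizontal axis left out. At 3 h the count was 701 without control_3h replicate 2, and at 25 h it was 525 without parasitized_25h replicate 1; every other bar stands at 0 or 1.

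Across both time points, CUST_804 (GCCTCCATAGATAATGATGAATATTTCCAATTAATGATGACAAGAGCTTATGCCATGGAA) and CUST_5593 had the smallest p for a mean difference between parasitized and control pupae. CUST_804 had a mean log2 difference of 0.38 ± 0.05 (SE; limma's adjusted p = 0.067), with levels of 8.97 and 9.34 in control and parasitized pupae at 3 h and of 8.08 and 8.53 at 25 h. CUST_5593 had 0.31 ± 0.04 (SE; limma's adjusted p = 0.067). On the lower side, CUST_5148 and CUST_7962 both had -0.24 ± 0.04 (SE; limma's adjusted p = 0.092). By limma 0 of 5815 probes passed, with 1081 at an unadjusted p under 0.05, and 160 passed with the log ratios scaled between arrays. With pupae weighted by their fit, chosen after seeing the data, 1399 passed, 621 higher and 778 lower. Without parasitized_25h replicate 1 the count was 369, 294 higher and 75 lower, without loop 1 it was 112, without control_3h replicate 2 it was 70, and without parasitized_3h replicates 3 and 4 in turn it was 2 and 4. Slides 1 and 2 alone gave 0 and 3, and the models with arrays as replicates gave 43 and 1154.

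Whether the effect of parasitization differed between the time points was tested by the interaction. CUST_8208 had a log2 interaction of 2.19 ± 0.35 (SE; limma's adjusted p = 0.29), as its difference between parasitized and control pupae was -0.44 ± 0.25 at 3 h and 1.75 ± 0.25 at 25 h. CUST_5810 had 0.65 ± 0.12, CUST_2698 had -0.27 ± 0.06 and CUST_6594 had -0.18 ± 0.04 (SE; limma's adjusted p = 0.29 for each). By limma 0 of 5815 probes passed, with 839 at an unadjusted p under 0.05. Weighting pupae by their fit, chosen after seeing the data, gave 1048. Without parasitized_25h replicate 1 the count was 256, without loop 1 it was 54, without control_3h replicate 2 it was 8, and without parasitized_3h replicate 1 or control_25h replicate 2 it was 1. Both slides alone gave 0, and the models with arrays as replicates gave 758 and 1281.

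The comparisons of 25 h with 3 h addressed the course of time in pupae of each condition. In control pupae, CUST_5764 (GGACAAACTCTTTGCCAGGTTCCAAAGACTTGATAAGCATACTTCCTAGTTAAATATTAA) rose 59.2-fold from 3 h to 25 h (log2 5.89 ± 0.57, SE; limma's adjusted p = 6.6e-05), from a log2 level of 8.65 ± 0.56 to 14.36 ± 0.48 (SD, n = 4). CUST_132 (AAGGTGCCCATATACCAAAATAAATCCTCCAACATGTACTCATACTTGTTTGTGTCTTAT) rose 44.5-fold (log2 5.48 ± 0.26, SE; limma's adjusted p = 7.5e-07). CUST_5111 (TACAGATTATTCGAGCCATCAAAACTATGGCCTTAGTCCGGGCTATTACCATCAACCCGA) fell 26.9-fold, with a log2 change of -4.75 ± 0.40 (SE; limma's adjusted p = 2.5e-05), from 11.39 ± 0.86 to 6.61 ± 0.52 (SD, n = 4). CUST_8208 fell 18.3-fold, with a log2 change of -4.19 ± 0.25 (SE; limma's adjusted p = 3.4e-06). These 4 probes moved in the same direction in all 4 loops. Over 39 alternatives the log2 changes were 5.5 to 6.31 (CUST_5764), 5.21 to 6.5 (CUST_132), -6.41 to -4.1 (CUST_5111) and -5.45 to -3.72 (CUST_8208). The size of the fold thus depends on the processing and the pupae used. On slide 2 alone CUST_5764 missed the threshold (log2 6.27; limma's adjusted p = 0.073, against 1.1e-13 to 0.073 over 39 alternatives). In total 1212 probes passed by limma, 696 higher and 516 lower at 25 h, and 23 rose and 18 fell at least 4-fold. The median size of a change among those called was log2 0.33. By the background flags alone, 15 probes were above background in all 8 readings at 25 h and in none at 3 h, and 8 the other way round. The share of higher calls depended on the processing. With the median of each array in place of loess, 622 were higher and 198 lower. With separate-channel pupa means, 606 were higher and 805 lower with the loop term, and 590 were higher and 703 lower without it. Slide 1 alone gave 364 calls and slide 2 alone gave 85. Leaving out 1 pupa gave 892 to 1370, and leaving out loop 1 or loop 3 gave 793 or 615. Weighting pupae by their fit gave 1820.

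In parasitized pupae, CUST_132 and CUST_5764 also rose and CUST_5111 also fell with time. CUST_132 rose 26.4-fold (log2 4.72 ± 0.26, SE; limma's adjusted p = 2.3e-06) and CUST_5764 rose 12.3-fold (log2 3.62 ± 0.57, SE; limma's adjusted p = 0.001). The latter stood at 10.81 ± 1.48 in parasitized pupae at 3 h, where its spread was the widest of the 4 groups (SD, n = 4). CUST_9596 (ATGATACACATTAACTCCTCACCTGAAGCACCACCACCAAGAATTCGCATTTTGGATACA) fell 5.64-fold (log2 change -2.50 ± 0.39, SE; limma's adjusted p = 0.00095), and CUST_5111 fell 5.55-fold (log2 change -2.47 ± 0.40, SE; limma's adjusted p = 0.0012), to 8.35 ± 0.49 (SD, n = 4). On slide 2 alone neither passed, with log2 changes of -2.59 and -1.56 (limma's adjusted p = 0.13 and 0.051, the highest over 39 alternatives of each, of which the lowest were 8.1e-09 and 3.7e-08). The 2 probes with the largest increase in all 4 loops, CUST_5586 (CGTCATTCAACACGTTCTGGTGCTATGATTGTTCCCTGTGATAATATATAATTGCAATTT) with log2 5.19 ± 1.80 (SE; limma's adjusted p = 0.047; above background in 3 of the 8 readings at 3 h and in 7 of the 8 at 25 h) and CUST_2467 with 4.87 ± 1.70 (SE; limma's adjusted p = 0.046), belong to the set of 155 probes with separate levels and did not part the time points: parasitized_25h replicate 4 was as low as the 3 h pupae in both. Under 23 of 35 alternatives CUST_5586 no longer passed, and under 21 of 36 CUST_2467 did not. In total 2000 probes passed by limma, 1185 higher and 815 lower at 25 h, and 1907 passed with the 155 probes left out. Since their level was low in all 4 parasitized pupae at 3 h and high in 3 of 4 at 25 h, it was also used as a covariate in these remaining probes: 1379 passed, 1139 of them among the 2000. By the background flags alone, 15 probes were above background in all 8 readings at 25 h and in none at 3 h, 7 of them also in controls. The other way round there was 1, also in controls. It was CUST_9509, chosen after its values were seen, at least 1.38-fold lower at 25 h (limma's adjusted p = 7.9e-05). With the scanner's processed signals 1015 were higher and 1130 lower, and with separate-channel pupa means 1061 were higher and 1131 lower with the loop term and 858 and 881 without it. Slide 1 alone gave 397 calls, slide 2 alone gave 188, and leaving out parasitized_25h replicate 2 or 3 gave 1259 or 1288. Without loop 2 or loop 3 the count was 1103 or 943.

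**Figure D2:**
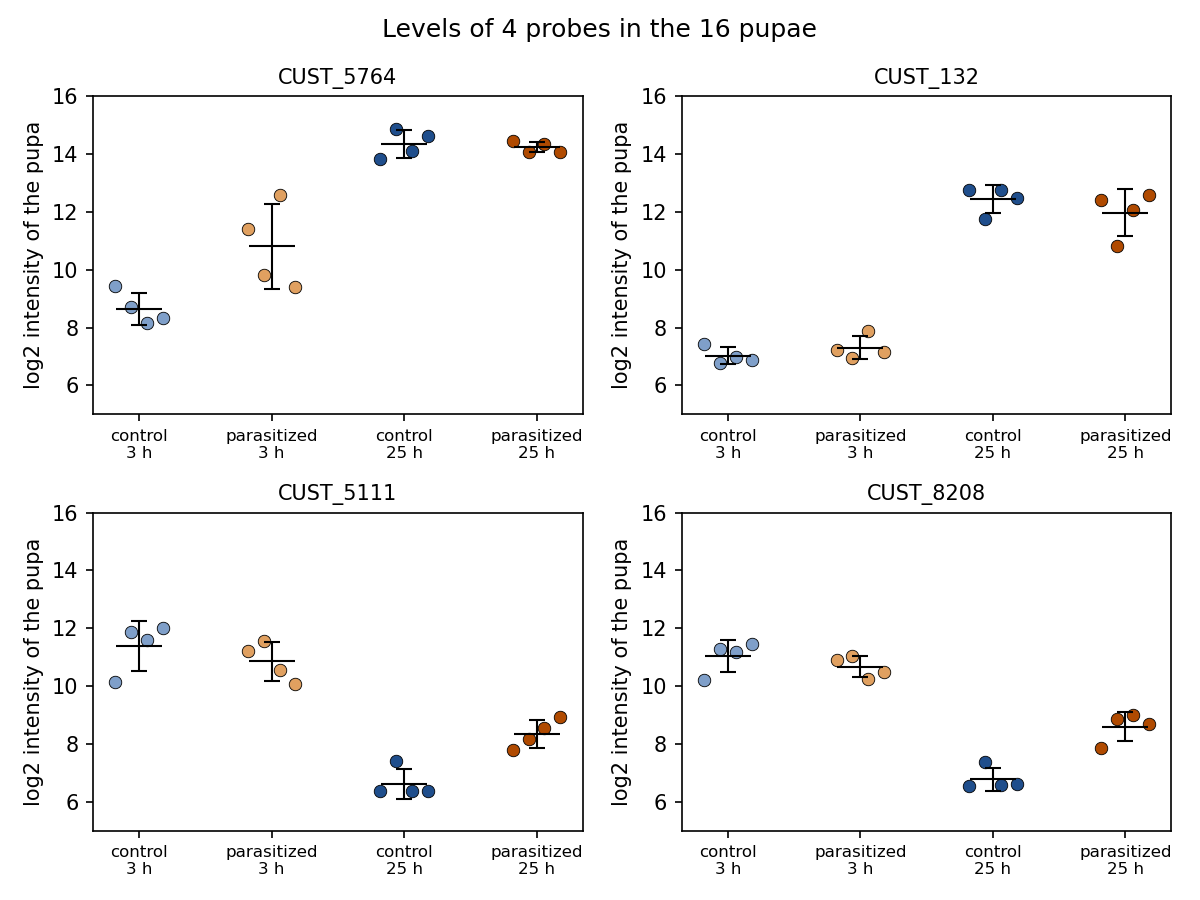
Log2 intensity (vertical axis) of 4 probes in each pupa (points), with the mean and SD of the 4 pupae of each group (bars). CUST_5764 and CUST_132 were higher at 25 h than at 3 h in both conditions, and CUST_5111 and CUST_8208 were lower, with mean levels at 25 h of 6.61 and 6.77 in control and 8.35 and 8.60 in parasitized pupae.

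Of the 2350 probes called for time in either condition, 2116 (90%) had the same sign in both. Among the probes called in each condition, 536 were higher at 25 h in both and 324 were lower in both, against 142 and 72 for independent lists, and 2 went in opposite directions. The log2 changes correlated across probes with r = 0.602 (Spearman's rho = 0.633), although probes are not independent replicates. The conditions share no pupa but share arrays. Groups without change simulated on the same loops gave a mean r of 0.0025 and a mean covariance of 7.3e-05 over 100 simulations, against 0.136 observed. The shared arrays alone thus added almost no correlation on average. The simulated noise was independent between probes, so it does not show how far r could move by chance in probes that vary together. The median change of the 536 was 0.44 in both conditions, and that of the 324 was -0.28 in control and -0.31 in parasitized pupae. A difference between the conditions in the change with time is the same contrast as the interaction above, for which 0 probes passed by limma and 839 had an unadjusted p under 0.05.

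**Figure D3:**
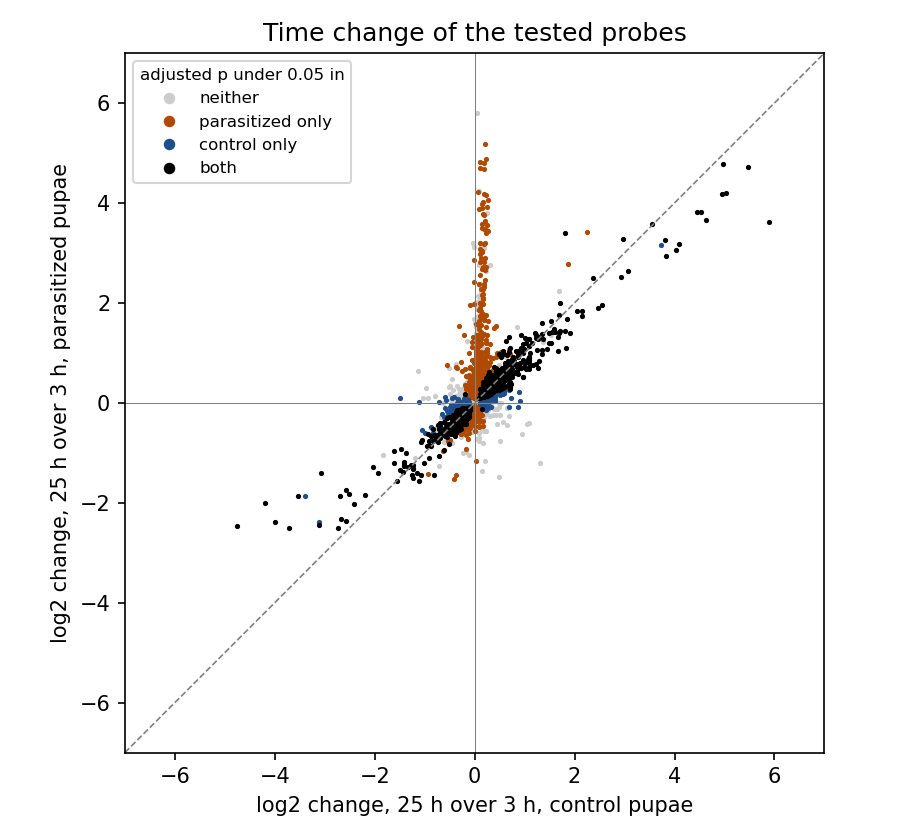
Log2 change from 3 h to 25 h of each of the 5815 tested probes in control pupae (horizontal axis) and in parasitized pupae (vertical axis); the colour gives the condition in which the change passed limma's adjusted p of 0.05, and the dashed line marks equal changes. The 536 and 324 probes called in both with the same sign lie along the dashed line, and the vertical streak at no change in controls holds the probes with separate levels.

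Some probes parted the pupae by neither time nor parasitization alone. A set of 155 probes, of 272 with a gap over 1 in their log2 levels, parted the same 9 pupae from the same 7, and no other division of more than 1 pupa had over 15 probes. The mean level of the set was 8.93 to 9.20 in 3 control pupae at 3 h and in 3 pupae of each group at 25 h. It was 6.03 to 6.27 in control_3h replicate 2, control_25h replicate 4, parasitized_25h replicate 4 and all 4 parasitized pupae at 3 h. The numbers of pupae at the upper level, 3 of 4 controls and 0 of 4 parasitized pupae at 3 h, gave a two-sided Fisher's exact p of 0.143. The first principal component, with 60.2% of the variance, parted the same pupae, and the second, with 21.3%, ran from between -23.5 and 0.2 in the 3 h pupae to between 4.3 and 24.5 in the 25 h pupae.

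**Figure D4:**
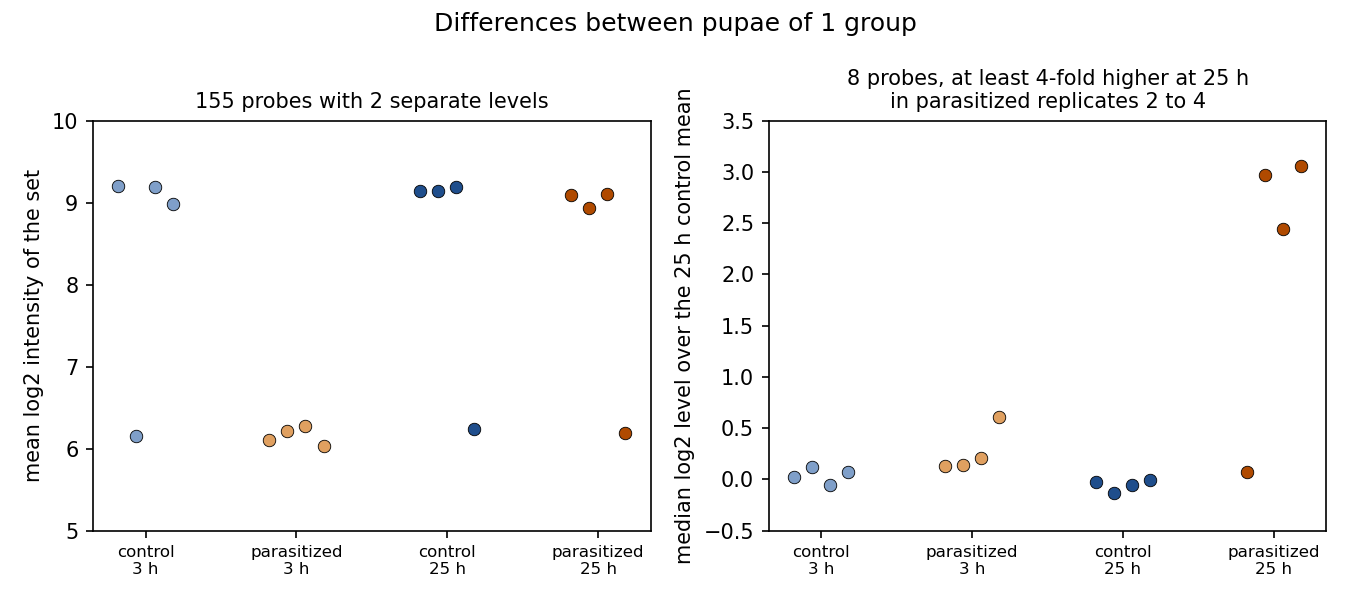
Left, mean log2 intensity of the 155 probes (vertical axis) in each pupa (points) by group; 9 pupae lie between 8.93 and 9.20 and 7 between 6.03 and 6.27. Right, median log2 level, relative to the mean of the 25 h controls, of the 8 probes at least 4-fold higher at 25 h in parasitized replicates 2 to 4, by which they were picked; parasitized_25h replicate 1 lies at 0.08.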

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

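All tests of the set of 155 probes and those of a later and an earlier time point for parasitized_3h replicate 4 were chosen, or put in their present form, only after the result was seen; the test of its hybridization was not. The time points were a single explanation at first, split after its value was seen, as was the difference between individuals. The largest gap to the nearest pupa, as a share of the range of a group of 4 and past Dixon's critical value, marked 19 of 108 groups of values, where chance marks about 1 in 20. The groups are not independent, and those of the 155 probes were picked for a gap, so the 19 cannot be judged against that rate.

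Most marked values belong to the 155 probes with separate levels. The set level was 6.15 in control_3h replicate 2 (others 8.99 to 9.20), 6.24 in control_25h replicate 4 (others 9.14 to 9.19) and 6.19 in parasitized_25h replicate 4 (others 8.93 to 9.11). In the same pupae CUST_5586 stood at 6.12, 6.30 and 6.21, at least 6 log2 units under its group, CUST_2467 at 6.30, 6.40 and 6.22, and the first principal component at 28.3, 16.2 and 17.9. Parasitized_25h replicate 4 also stood apart on the second component, at 24.5 against 5.1 to 7.8; control_25h replicate 4, of the same loop and also at the lower level, lay at 22.2 there, with the other controls at 4.3 to 8.1.

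In 16 of 16 pupae both readings, from different labelling reactions and arrays, fell on the same side of the gap. This speaks only weakly against an effect of dye or array, since the probes were picked by the mean of both readings, which favours agreement. That parasitization alone sets the level is argued against, since 5 pupae lay on the side that their treatment would not give. Other RNA carried over in varying amounts would spread the upper levels, and their spread was 9.84% of the gap. Picking probes by a wide gap between these pupae favours a narrow spread, so this too speaks only weakly against carry-over. A difference in which each state has transcripts of its own would need probes high in the 7 pupae and low in the 9, and 0 were found with a gap over 1 (2 at a gap over 0.5, against 212 in the main direction). A difference with transcripts present in 1 state only, such as an organ of 1 sex, which the labels do not give, stays open. Of the pupae, 0 lay in the middle of the gap, but the probes were picked for that gap. Such a difference therefore cannot be told apart from other causes. An effect of parasitization at 3 h beside it stays open too, with 3 of 4 controls and 0 of 4 parasitized pupae at the upper level (two-sided Fisher's exact p = 0.143).

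Parasitized_3h replicate 4 lay at 26.9 on the third component, against -10 to -7.1 for the rest of its group. It stood alone, by a log2 gap over 1, above all other pupae in 31 probes and below all in 29, while no other pupa stood alone in more than 3 probes. A poor hybridization would leave the deviations of its 2 readings unlike, and they correlated across probes with r = 0.971. Of its 60 probes, 17 had changed with time in control pupae, and 5.88% of these lay toward the 25 h level, but probes that stand outside all other pupae, those at 25 h included, leave out any that lie between the times, so this decides neither for nor against a later or an earlier point of the time course. Over the probes that changed with time in controls, without the set of 155, the mean deviation of each parasitized 3 h pupa from the other 3 was 4.89%, -1.56%, 18.4% and, in replicate 4, -21.7% of the change, toward 25 h where positive. With 1 pupa against 3 that differ among themselves, a later and an earlier point both stay open, as do other differences between individuals.

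Single values were also marked for other named probes. CUST_8208 stood at 7.37 and CUST_5111 at 7.39 in control_25h replicate 2, against 6.53 to 6.62 and 6.35 to 6.36 in the other controls. CUST_5106 stood at 9.57 in control_25h replicate 4 (others 9.15 to 9.22), CUST_3275 at 5.95 in control_3h replicate 1 (others 6.02 to 6.03) and CUST_6594 at 7.30 in parasitized_25h replicate 3 (others 7.39 to 7.41).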

How the results depend on the processing

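Alternatives with the level of the 155 probes as a covariate, without these probes, with separate-channel means and the loop term, with weighted pupae, or without 2 pupae together were chosen after seeing the data. Of 928 values of named probes under alternatives, 769 stayed on their side of the threshold with their direction, 112 newly passed it, 47 no longer passed, and 0 changed sign. The named probes were picked for the same sign in all 4 loops. A change of sign was therefore hardly possible where a loop, slide or pupa was left out. The causes of the changes below were not tested, unless the construction shows them. Taking the 16 ratios as independent gave 614, 370, 758 and 43 probes for parasitization at 3 h, at 25 h, the difference between the times and the mean, and the separate-channel model gave 1159, 914, 1281 and 1154 (2086 and 3236 for time in control and parasitized pupae); both count the 2 readings of a pupa as replicates, which makes the spread too small. Weighting pupae by their fit gave 859, 1241, 1048 and 1399, and 1820 for time in controls. Scaling between arrays gave 166 at 25 h and 160 for the mean. At 25 h the processed signals and the authors' values gave 1 probe each, and without background subtraction the mean effect had 3. Slide 2 alone gave 4 at 25 h and 3 for the mean. For time, slides 1 and 2 alone gave 364 and 85 in controls and 397 and 188 in parasitized pupae, with fewer pupae. Median centring gave 1292 for time in parasitized pupae. The covariate, in fits that also leave the 155 probes out, gave 162 at 25 h (152 higher) without the replicate block and 0 with it; at 3 h the unadjusted count was 1027 with the probes left out and 471 with the covariate too. Without parasitized_25h replicate 1 and parasitized_3h replicate 4 together, the counts were 623 at 25 h, 245 for the difference and 423 for the mean.

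Leaving out a loop or a pupa gave 0 to 701 at 3 h, 0 to 525 at 25 h, 0 to 256 for the difference, 0 to 369 for the mean, 615 to 1370 for time in controls and 943 to 2177 for time in parasitized pupae. Without loop 1, 285 probes passed at 25 h, 281 of them among the 525 called without its parasitized pupa.

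The fit without the replicate block needs separate-channel pupa means, so it changes the values too. It gave 0 probes in each of the 4 parasitization comparisons, and 1293 and 1739 for time in control and parasitized pupae, 1031 and 1500 of them shared with the calls above. The same means with the replicate block gave 0 at 3 h and for the difference, 4 at 25 h, 10 for the mean, and 1411 and 2192 for time. Same-numbered pupae deviated together with a correlation over 0.1 in 16 of 24 pairs (median 0.14, -0.7 to 0.91). Other pupae of different groups had a median of 0.013 (-0.88 to 0.94). In 9 of 16 pupae the deviation was most like that of the others of their own number. Whether same-numbered pupae share more than a loop stays open. Averaging several probes of a gene and the gene list tests were not run, since the files name no genes. Signal over background limits the results to 57.4% of the probes.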

Other observations

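The test of strong falls with time was chosen only after the result was seen; the other tests of this part were not, apart from the test of swapped labels.

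Probes with a strong fall in time had a smaller fall in the parasitized than in the control pupae of each loop. For each loop, probes called in both conditions with a mean log2 fall over 1 were picked in the other 3 loops, by the mean of both conditions, and read in the loop left out. The falls in control pupae were -1.79, -1.99, -2.13 and -1.89 in loops 1 to 4, over 31, 26, 30 and 46 probes, and those in parasitized pupae were -1.66, -1.76, -1.18 and -0.81. The fall was thus smaller in the parasitized pupae of 4 of 4 loops; with 4 pairs, an exact two-sided sign test cannot give a p under 0.125. Probes picked for a mean rise over 1 showed no such order, with 1.81, 1.89, 2.41 and 2.77 in control and 1.87, 1.38, 1.60 and 3.04 in parasitized pupae. A general slowing of the change with time would lower it in all 4 loops, and over all shared time probes it was lower in 3 of 4 (0.61, 0.63, 0.83 and 0.67 in control against 0.66, 0.55, 0.57 and 0.66 in parasitized pupae). The exception was loop 1. Its parasitized 25 h pupa showed little of the shift described in the next paragraph, so the 3 of 4 do not decide against a slowing. A hypothesis is that parasitized pupae may keep transcripts that other pupae lose by 25 h, of which CUST_8208 and CUST_5111, both picked by their fall in controls, would be examples. A smaller fall can also come from a lower level in parasitized pupae at 3 h, and the held-out changes do not tell these apart. The difference between parasitized and control pupae was log2 -0.60 at 3 h and 1.68 at 25 h for CUST_5111, and -0.44 and 1.75 for CUST_8208. For CUST_3382, which also fell in controls, this difference was -0.53 and 0.215, so most of it lay at 3 h. CUST_8208 was also picked by its difference at 25 h and by its interaction, so it is no separate support. The hypothesis does not cover the 8 probes at least 4-fold higher, of which 0 fell with time in controls past limma's threshold, and whose median in the 3 h pupae was log2 -0.05 to 0.61 from the 25 h controls. In the test of the difference itself, 0 probes passed by limma, with 839 at an unadjusted p under 0.05.

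The shift at 25 h was seen in the parasitized pupae of 3 loops. Over the 500 probes with the smallest p, picked without a loop and read in it, the parasitized pupae of loops 2, 3 and 4 were shifted from the controls by log2 0.38, 0.33 and 0.50 in the direction found in the other loops. The control pupae of loops 1 to 4 had shifts of -0.00276, 0.07, 0.05 and 0.07. Parasitized_25h replicate 1 had 0.0256, within the range of the controls. The parasitized pupa had the higher shift in 4 of 4 loops (exact sign-flip p = 0.125, two-sided, the smallest p of this design). A swap with the control pupa of the same loop is argued against, since that pupa had -0.68% of the mean shift of the other parasitized pupae, and a poor hybridization is too, since neither reading of replicate 1 exceeded 9.62%. That the response was absent or weaker in this pupa, or that it was not parasitized, is consistent with its shift of 0.0256 and stays open as a hypothesis.

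Other splits of the same pupae were counted for each comparison. For time in control pupae, 1 of the 35 splits, the real one, gave 1212 probes, and the highest other gave 0. For time in parasitized pupae, 1 of 35 gave 2000, and the highest other gave 326. Of the 35, 8 put 1 pupa of each loop on each side, as the real split does, and the highest other among them gave 0 for both. The rest are not balanced over the loops, which are a term of the fit, so they are not like the real split. The 8 are too few for a share under 0.125, so the splits alone cannot exclude chance. For parasitization the real split gave 0 probes, which any split reaches (35 of 35 at 3 h and at 25 h, 100 of 100 drawn for the difference and for the mean), so this count decides nothing. The highest other splits gave 784 at 3 h, 1 at 25 h, 626 for the difference and 425 for the mean. The 784 and the 326 came from splits with pupae of a loop on the same side, and splits that keep the loops gave at most 2 at 3 h. Splits with so many probes point to a structure of the pupae. At 3 h the splits with 784, 626 and 425 probes were all the real one with control_3h replicate 2 and parasitized_3h replicate 4 exchanged. Like the real split, they hold the 3 control pupae at the upper level of the 155 probes on 1 side. At 3 h every other split that does so gave 0, so the level of the set alone does not account for the 784. The make-up of the splits was read after their counts were seen, and why this exchange gave calls was not tested.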
